A study of Homo sapiens with 6 samples.

How the data were processed

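Gene expression was measured by RNA sequencing of poly(A)-selected RNA from MM.1S cells, with 2 libraries each for scramble control, IRF3 shRNA 1 and IRF3 shRNA 2, per the labels. Groups were taken from the shRNA that the labels give each library. Salmon 0.12.0, a transcript quantifier, DESeq2 1.24.0 and the genome build GRCh38 (hg38) are named in the submitters' processing notes, without their settings. Read length, the transcript annotation and the use of strand are not given in the sources used here. Salmon divides reads that fit several transcripts by a model, so levels of close copies and of overlapping genes are estimates.

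The analysis used 2 tables of comparisons that the authors deposited, shRNA 1 against scramble and shRNA 2 against scramble. Their first measurement is a signal in normalised read counts, the mean over the libraries that the authors fitted, as the column baseMean in the file headers. The log2 fold changes and their SEs are on the log2 scale as the authors deposited them. The Wald score deposited by the authors is the log2 fold change divided by its SE, which held in the files to within 3.27e-07. The p-values and adjusted p-values are also those the authors deposited. The means were identical in both tables for all 33095 genes, as in a fit of all 6 libraries together. Adjusted p-values are present for 14488 genes with shRNA 1 (lowest mean 26.8) and 17054 with shRNA 2 (lowest mean 11.8), because low genes carry none, and genes without one were left out of counts. The main test of each comparison was therefore the authors' own DESeq2 result at an adjusted p below 0.05. No value of a single library was available in the tables used here, so no count test was run, no library was left out in turn and no replicate block was fitted.

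Fold changes are coded as shRNA over scramble. The plan was to read this from IRF3, for which no fall was detected in the second comparison. The coding was therefore checked without IRF3, on dispersions solved from each table for 1388 genes. They had a median absolute log ratio of 0.00671 as coded, 0.169 with the sign of the second table turned, 0.0856 with that of the first turned and 0.130 with both turned. The last pair of values was added after the results were seen. For genes with a mean under 5 the log2 fold changes correlated at 0.482, against 0.524 in a simulation of shared controls with no effect. Group means, dispersion and the variance of each group mean were then reconstructed from the mean and from both fold changes and SEs of each gene. A reconstructed mean is named as such where it is printed.

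All 33095 gene identifiers occur in GENCODE 29 (GRCh38), from which coordinates, exons and transcript sequences were taken. Symbols are those in the deposited tables, which name 20077 genes, and older symbols were matched to current ones. Mitochondrial transcripts made up 12.1% of the summed means. The median log2 fold change of genes with a mean of 50 or more was -0.04 in both comparisons.

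The difference between the hairpins was tested by z, the difference of the 2 log2 fold changes over the root of the summed squared SEs, two-sided, with Benjamini-Hochberg adjustment. The shared scramble libraries make this SE too large. Unchanged groups against shared controls were simulated 100 times. Gene lists, 31 in all, were fixed before the data were examined. A list with at least 5 tested members was tested with limma's cameraPR (limma 3.58.1, R 4.3.3) on the deposited Wald score with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation needs values of single libraries and was not computed. Median fold changes of lists were compared with 10000 random lists of equal size matched on mean expression. Of the lists tested, 28 had enough members with shRNA 1 and 30 with shRNA 2.

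Named genes followed a rule fixed before the data were examined. It took IRF3, the 12 higher and 12 lower genes with the largest smaller change among those passing in both comparisons at a mean of 50 or more, and 4 higher and 4 lower genes that passed with each hairpin and not with the other. It further took up to 4 members of each list with the lowest larger p, the 4 genes with the lowest p of the difference, and BCL2L12, IRF4, PRDM1, MYC, SDC1 and IRF7. Another 2 genes that the rule takes are not reported here. Genes without a unique symbol, immunoglobulin and T cell receptor segments and pseudogenes were left out of the ranking, which removed 1301 of 12977 genes.

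Alternatives covered the threshold, a fold change minimum, the filter on low genes, recentring on the median gene, the SE of the difference, and the correlation, ranking and form of the list test. For the closing section, all sequences of 7 bases in 3' UTRs were scanned in 11310 protein-coding genes with a mean of 50 or more, by the mean residual log2 fold change of genes holding the sequence. The residuals were taken after regression on 3' UTR length, base composition and expression, with fold changes limited to 3 either way, sequences in at least 30 genes, and 200 permutations of genes.

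Several steps were tested on simulated data, under settings simpler than the data. The z test of the difference recovered 67.4% of 92 genes changed by 1 on the log2 scale and 88.3% of 94 changed by 2. Among 14488 simulated genes it called 0 unchanged genes, with the dispersions taken as known and few genes changed. With the reconstructed SE it recovered 81.5% and 95.7%, and 5.06% of its calls were unchanged genes. The scan ranked a planted sequence first in 20 of 20 runs. Its planted shift of 0.2 was larger than the mean residuals of -0.127 and -0.117 found for the leading sequences. The list test called 0 of 100 unchanged lists, drawn at random with independent scores. That result does not cover lists whose members vary together. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.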

Results

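MM.1S is an established human cell line of multiple myeloma, a cancer of antibody-secreting plasma cells. The cells carried, through lentiviral transduction, either a scrambled control hairpin or 1 of 2 short hairpin RNAs (shRNAs) directed against IRF3, a transcription factor that is activated by nucleic acid sensing and induces type I interferon. Poly(A)-selected RNA was sequenced from 2 libraries per arm, 6 libraries in all. The values analysed are the authors' deposited tables of 2 comparisons, shRNA 1 against scramble and shRNA 2 against scramble. Each table lists 33095 genes with the mean normalised read count over the fitted libraries, the log2 fold change, its standard error (SE), a p-value and an adjusted p-value. The tables used here hold no value of a single library, so the depth of each library is unknown and no standard deviation of replicates is given. The mean normalised read counts sum to 25062897 in the authors' deposited tables. The median SE of a log2 fold change was 0.36 for the 2812 genes with a mean of 50 to 200, 0.174 for the 5018 genes from 200 to 1000 and 0.106 for the 5147 genes from 1000 upwards, so that small changes were detectable mainly in abundant transcripts. The labels do not say whether the 2 libraries of an arm came from separate cultures, and the p-values therefore measure only the spread between these libraries, which may be technical.

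The first question was whether the targeted transcript was lower. The direction of coding was checked on the dispersions of other genes, whose values from both tables agreed best as coded, so the sign of the change does not rest on IRF3 itself. IRF3 (ENSG00000126456, chromosome 19, 49659569 to 49665875, minus strand, GRCh38) had a log2 fold change of -1.53 ± 0.10 (SE) with shRNA 1 in the authors' deposited table, with a DESeq2 adjusted p of 8.45e-46. This was 0.347 times the scramble level, with a 95% interval of 0.301 to 0.400. With shRNA 2, the authors' deposited table gives IRF3 a log2 fold change of -0.18 ± 0.10 (SE) and a DESeq2 adjusted p of 0.181, a ratio of 0.881 with an interval of 0.768 to 1.01. A fall of IRF3 was therefore not detectable in the libraries labelled shRNA 2, and the interval leaves out a fall as large as that with shRNA 1. The 2 log2 fold changes differed by 1.35 ± 0.15 (SE), with an adjusted p of 2.93e-18 in a two-sided z test on the authors' deposited values. Directions given below for shRNA 2 are those of libraries labelled as such, in which the targeted mRNA was not shown to be lower. BCL2L12, a gene on the opposite strand whose annotated exons overlap those of IRF3, had log2 fold changes of -0.05 ± 0.17 and -0.34 ± 0.17 (SE) in the authors' deposited tables and passed in neither. Reads from the overlapping part cannot be assigned with certainty, since the use of strand in the counting is not given in the sources used here. Among the 10 tested neighbours of IRF3 on chromosome 19, AP2A1 (-0.50 with shRNA 1) was the 1 gene that changed with shRNA 1, and 1 rose and 1 fell with shRNA 2, per the authors' deposited tables (the counts adjusted over the list alone were identical).

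**Figure D1:**
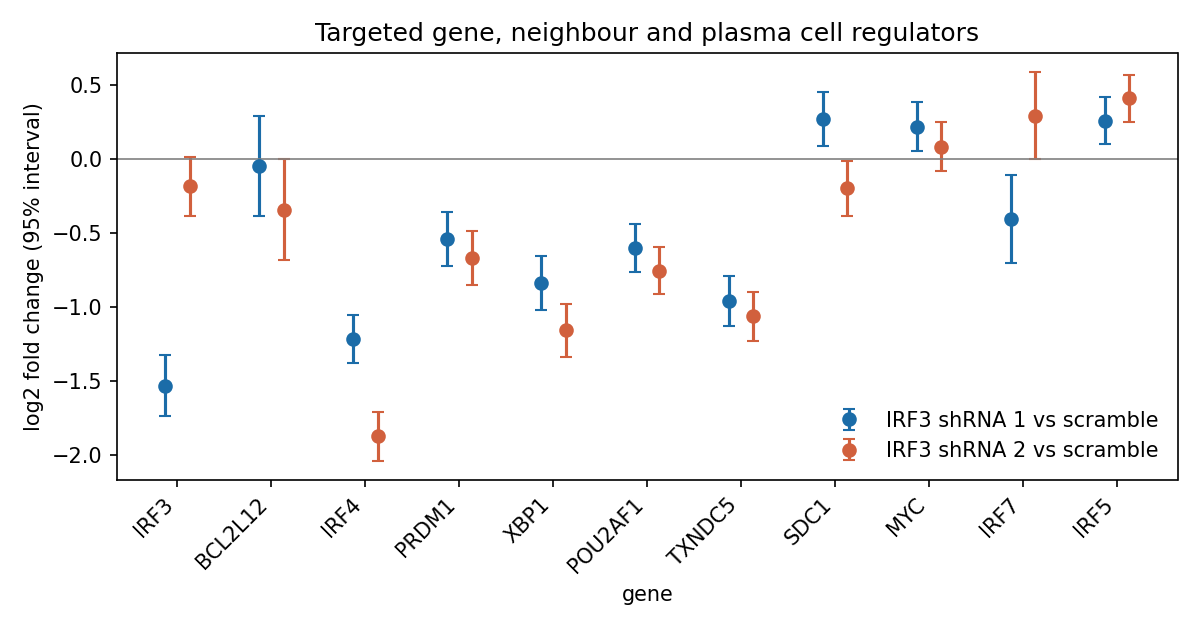
The vertical axis gives the log2 fold change against scramble from the authors' deposited tables, with 95% intervals, for 11 genes on the horizontal axis; blue is shRNA 1 and orange the libraries labelled shRNA 2. IRF3 lies at -1.53 with shRNA 1 and at -0.18 with shRNA 2, while IRF4 lies at -1.21 and -1.87.

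The next comparison asked what changed in the cells with shRNA 1. As lists, plasma cell, DNA replication, unfolded protein response and cholesterol synthesis genes were lower in the main list test. Ribosomal protein, MHC class II and immediate early genes were higher as lists, though many members of these lists were not called. IRF4 (chromosome 6, 391739 to 411447), the transcription factor on which myeloma cells depend, had a log2 fold change of -1.21 ± 0.08 (SE), a ratio of 0.432, in the authors' deposited table. At an adjusted p below 0.05, 3571 of 14488 genes with an adjusted p had changed, 1420 higher and 2151 lower, per the authors' deposited table. Recentred on the median gene, 3533 had changed, 1699 higher and 1834 lower, so most of the surplus of lower genes depended on the centring. Unadjusted p was below 0.05 for 5080 genes. TMED9 (chromosome 5, 177592158 to 177596124), a cargo receptor of the early secretory pathway, had a log2 fold change of -2.13 ± 0.09 (SE) in the authors' deposited table, a ratio of 0.229.

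Of 30 tested plasma cell genes, 14 were lower and 5 higher with shRNA 1 (15 and 5 adjusted over the list alone), with a median log2 fold change of -0.18, computed from the authors' deposited table. These included XBP1, the transcription factor of the secretory programme, at -0.83 ± 0.09, the plasma cell regulator PRDM1 at -0.54 ± 0.09, POU2AF1 at -0.60 ± 0.08 and TXNDC5 at -0.96 ± 0.09 (SE) in the authors' deposited table. The surface antigen SDC1 went the other way, at 0.28 ± 0.09 (SE) with a DESeq2 adjusted p of 0.0172 in the authors' deposited table. The list test, limma's cameraPR on the authors' deposited statistic, gave an adjusted p of 6.97e-05, which became 0.0891 when genes were ranked by log2 fold change and 0.0586 in the rank-based form. Of 23 unfolded protein response genes, 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.28 and a list adjusted p of 0.000106 (0.0891 when ranked by log2 fold change), from the authors' deposited table. SEL1L, part of the degradation machinery of the endoplasmic reticulum, was at -1.07 ± 0.09, the stress sensor ERN1 at -0.66 ± 0.09 and DNAJC3 at -0.59 ± 0.10 (SE) in the authors' deposited table. Of 28 cholesterol synthesis genes, 11 were lower and 1 higher (14 and 1 adjusted over the list alone), per the authors' deposited table. The list median was -0.28, with a list adjusted p of 0.00208. The fatty acid desaturase SCD was at -1.21 ± 0.10 and the lipogenic transcription factor SREBF1 at -1.01 ± 0.11 (SE) in the authors' deposited table.

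DNA replication and S phase genes were lower in 25 of 48 cases and higher in 0 with shRNA 1 (27 and 0 adjusted over the list alone), per the authors' deposited table. Their median was -0.36 and the list adjusted p 5.95e-07. E2F1, a transcription factor of S phase entry, was at -1.04 ± 0.13, the replicative helicase subunits MCM6 and MCM3 at -0.77 ± 0.10 and -0.63 ± 0.08, and the flap endonuclease FEN1 at -0.92 ± 0.12 (SE) in the authors' deposited table. Of 47 mitosis genes, 11 were lower and 1 higher (the same counts adjusted over the list alone), and the list did not pass, with a median of -0.19 and an adjusted p of 0.308 on the authors' deposited statistic. Cytosolic ribosomal protein genes were higher in 42 of 77 cases and lower in 1 (47 and 1 adjusted over the list alone), per the authors' deposited table. This gave a median of 0.22 and a list adjusted p of 1.08e-13. RPS24 was at 0.83 ± 0.09 and RPS28 at 0.80 ± 0.07 (SE) in the authors' deposited table; reads of such genes are shared with many processed pseudogenes, and their levels are uncertain for that reason.

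Of 16 MHC class II genes, 9 were higher and 1 lower with shRNA 1 (10 and 1 adjusted over the list alone), per the authors' deposited table. Over the list the median was 0.62, and its adjusted p was 5.95e-07. HLA-DRA was at 0.83 ± 0.09, HLA-DPA1 at 1.25 ± 0.12, HLA-DPB1 at 0.75 ± 0.14 and HLA-DQA1 at 2.97 ± 0.36 (SE) in the authors' deposited table. HLA genes resemble each other and differ between genomes, so the division of their reads is uncertain. Immediate early genes were higher in 10 of 25 cases and lower in 1 (the same counts adjusted over the list alone), per the authors' deposited table. The list median was 0.25, with a list adjusted p of 6.97e-05. The transcription factors KLF2, JUN and ATF3 were at 1.03 ± 0.16, 0.93 ± 0.11 and 0.91 ± 0.14 (SE) in the authors' deposited table. Hypoxia and glycolysis genes were higher in 12 of 27 cases and lower in 5 (13 and 6 adjusted over the list alone), per the authors' deposited table. Their median was 0.25 and the list adjusted p 0.000106. That call was lost when genes were ranked by log2 fold change (adjusted p of 0.0891) and in the rank-based test (adjusted p of 0.0749). Lactate dehydrogenase A (LDHA) was at 0.93 ± 0.08, the glucose transporter SLC2A1 at 1.41 ± 0.15, and NDRG1 at -0.60 ± 0.09 (SE) in the authors' deposited table.

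A further 7 lists passed with shRNA 1. Adjusted p-values from the authors' deposited statistic were 0.0237 for p53 targets (median 0.23, 8 higher and 5 lower of 32), 0.0463 for NF-kappaB targets (median 0.06, 8 and 2 of 24) and 0.0463 for ligands of NK and T cells (median 0.17, 5 and 0 of 17). Adjusted over the list alone, these counts were 9 and 5, 8 and 3, and 5 and 0. They were 0.0323 for replication-dependent histones (median 0.74, 3 and 0 of 10), and 0.0238 both for genes of the mitochondrial genome (median -0.15, 0 and 6 of 13) and for nuclear oxidative phosphorylation genes (median -0.19, 1 and 11 of 36), from the authors' deposited table. Adjusted over the list alone, these counts were 5 and 0, 0 and 8, and 2 and 16. Transcripts of replication-dependent histones are little polyadenylated, and their level in poly(A)-selected libraries depends on library chemistry. The histone list was higher here, with 3 of 10 genes passing, while the S phase list was lower. With a preset correlation of 0.05 in place of 0.01, the adjusted p-values of these 6 lists became 0.137, 0.167, 0.137, 0.0888, 0.0885 and 0.137, and none passed. The p53 and histone lists kept the call when ranked by log2 fold change (adjusted p of 0.0204 and 6.98e-05) and in the rank-based test (0.0225 and 0.0147). The interferon regulatory factor family passed as lower (adjusted p of 0.0181, median -0.01, 1 higher and 3 lower of 9, the same counts adjusted over the list alone), and lost the call without IRF3 itself (adjusted p of 0.407), on the authors' deposited statistic. IRF5 was at 0.26 ± 0.08 and IRF7 at -0.40 ± 0.15 (SE) in the authors' deposited table, the call of IRF7 being lost without the filter on low genes and on recentring.

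The third comparison asked the same of the libraries labelled shRNA 2. Every tested DNA replication gene and every tested mitosis gene was lower in these libraries. As lists, plasma cell genes were lower and ribosomal protein and p53 target genes higher, with some members not called or moving the other way. At an adjusted p below 0.05, 4939 of 17054 genes with an adjusted p had changed, 1852 higher and 3087 lower, per the authors' deposited table. Recentred on the median gene, 4951 had changed, 2158 higher and 2793 lower. Unadjusted p was below 0.05 for 6436 genes. The 48 DNA replication genes had a median log2 fold change of -1.83, a ratio of 0.281, and the 47 mitosis genes a median of -1.70, a ratio of 0.308, from the authors' deposited table. The list adjusted p-values were 1.51e-96 and 2.11e-51, and the counts of 48 and 47 lower genes were unchanged when adjusted over the list alone. E2F1 was at -2.48 ± 0.14, MCM6 at -2.17 ± 0.10, the kinesin KIF11 at -1.57 ± 0.11 and the spindle checkpoint gene MAD2L1 at -1.70 ± 0.15 (SE) in the authors' deposited table. The list of cyclin D, CDK and CDK inhibitor genes also holds RB1, RBL1, RBL2, E2F3, E2F4, E2F5, CDC25A, WEE1 and TFDP1. Of its 19 tested genes, 10 were lower and 2 higher (12 and 2 adjusted over the list alone), per the authors' deposited table. This gave a median of -0.41 and a list adjusted p of 1.11e-06. The mitotic inhibitor kinase WEE1 was at -1.71 ± 0.14 and CDK4 at -0.83 ± 0.13, whereas CDK6 was at 0.70 ± 0.10 (SE) in the authors' deposited table.

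Of 32 plasma cell genes, 20 were lower and 5 higher in the libraries labelled shRNA 2 (22 and 6 adjusted over the list alone), per the authors' deposited table. Over the list the median was -0.43, and its adjusted p was 5.29e-13. IRF4 was at -1.87 ± 0.08, a ratio of 0.273, XBP1 at -1.15 ± 0.09, PRDM1 at -0.66 ± 0.09 and TXNDC5 at -1.06 ± 0.09 (SE) in the authors' deposited table. SDC1 was at -0.20 ± 0.09 (SE) and did not pass, with a DESeq2 adjusted p of 0.107 in the authors' deposited table. Unfolded protein response genes were lower in 16 of 23 cases and higher in 0 (the same counts adjusted over the list alone), per the authors' deposited table. The list median was -0.40, with a list adjusted p of 1.47e-09. Cholesterol synthesis genes were lower in 20 of 28 cases and higher in 1 (21 and 1 adjusted over the list alone), per the authors' deposited table. Their median was -0.53 and the list adjusted p 1.38e-09. SCD was at -2.05 ± 0.10, while the sterol reductase TM7SF2 was at 1.02 ± 0.16 (SE) in the authors' deposited table. Ribosomal protein genes were higher in 70 of 77 cases and lower in 0 (73 and 0 adjusted over the list alone), per the authors' deposited table. This gave a median of 0.38 and a list adjusted p of 8.71e-29. Of 32 p53 target genes, 16 were higher and 3 lower (the same counts adjusted over the list alone), per the authors' deposited table. Over the list the median was 0.38, and its adjusted p was 4.87e-05. The death receptors TNFRSF10B and FAS were at 1.02 ± 0.11 and 0.81 ± 0.16, and the DNA polymerase gene POLH at -0.71 ± 0.13 (SE) in the authors' deposited table.

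Hypoxia and glycolysis genes were lower in 18 of 28 cases and higher in 4 in the libraries labelled shRNA 2 (19 and 4 adjusted over the list alone), per the authors' deposited table. The list median was -0.44, with a list adjusted p of 5.86e-07. LDHA was at -1.09 ± 0.08 and SLC2A1 at 0.94 ± 0.15 (SE) in the authors' deposited table. Immediate early genes were lower in 11 of 26 cases and higher in 2 (12 and 3 adjusted over the list alone), per the authors' deposited table. Their median was -0.53 and the list adjusted p 7.26e-06. KLF2 was at -3.51 ± 0.19 and JUN at -0.95 ± 0.11, and IER5 was at 0.96 ± 0.10 (SE) in the authors' deposited table. Nuclear oxidative phosphorylation genes were lower in 19 of 36 cases and higher in 0 (20 and 1 adjusted over the list alone), with a median of -0.30 and a list adjusted p of 2.11e-05, which became 0.0985 when genes were ranked by log2 fold change, from the authors' deposited table. ATP5F1B, of the ATP synthase, was at -0.53 ± 0.07 and UQCRC1, of complex III, at -0.53 ± 0.10 (SE) in the authors' deposited table. Targets of ATF4 and CHOP were lower in 12 of 30 cases and higher in 2 (the same counts adjusted over the list alone), with a median of -0.43, from the authors' deposited table. Their list adjusted p of 0.0160 became 0.12 with a preset correlation of 0.05 and 0.0805 when ranked by log2 fold change.

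**Figure D2:**
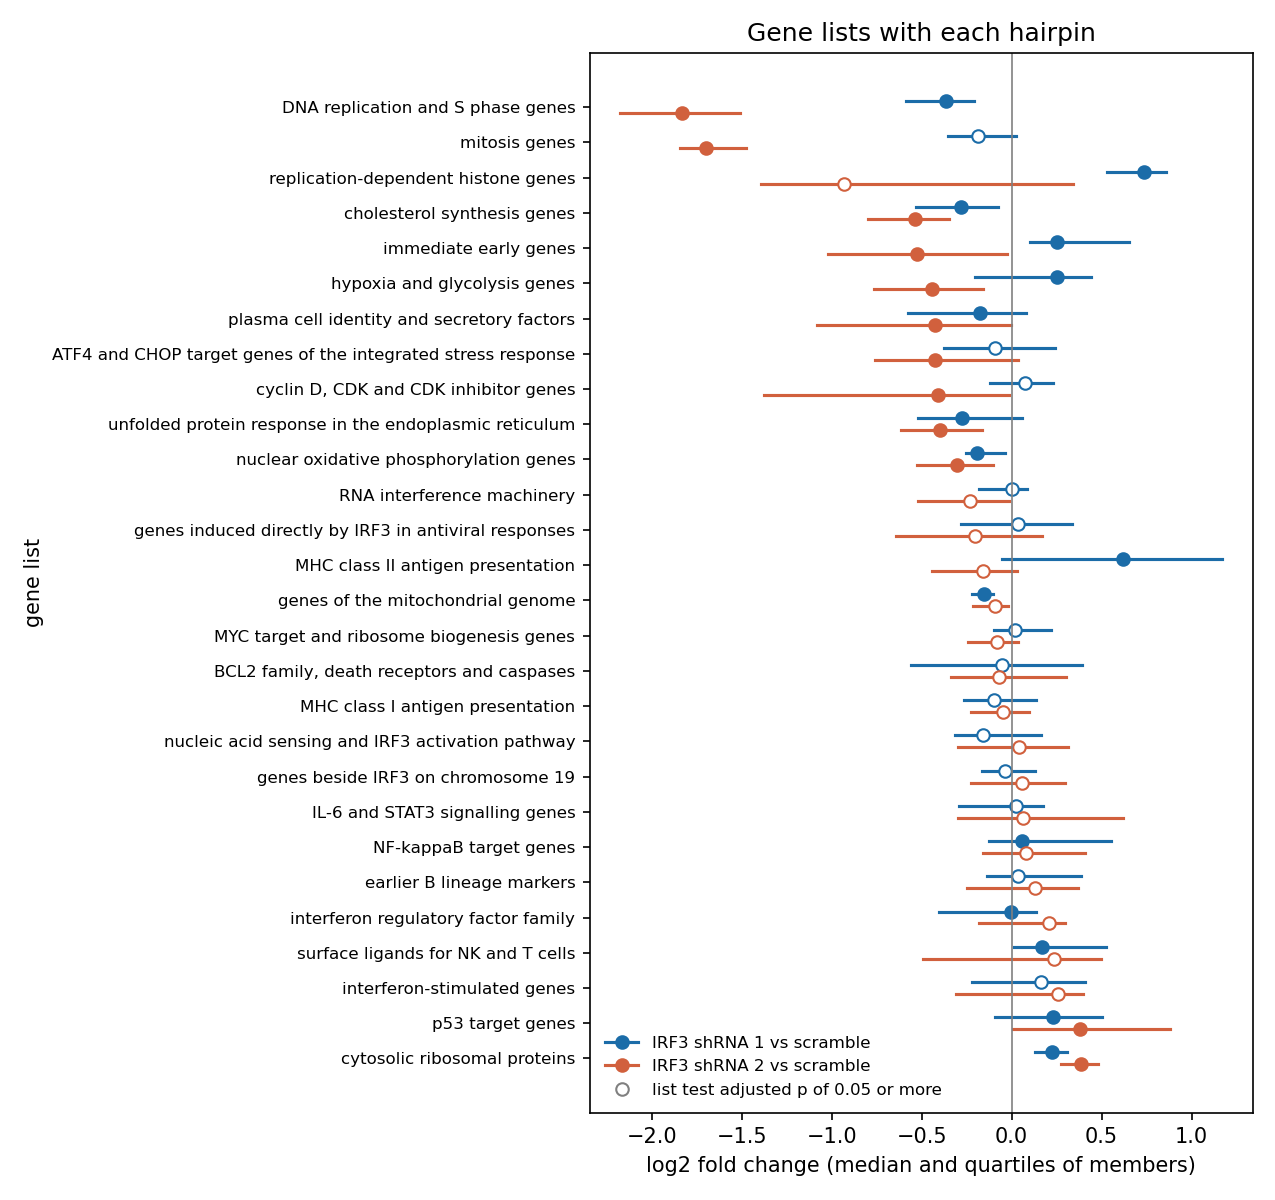
Points give the median log2 fold change of each fixed gene list (vertical axis) and lines its quartiles, computed from the authors' deposited tables, for shRNA 1 (blue) and the libraries labelled shRNA 2 (orange); open points mark lists with a cameraPR adjusted p of 0.05 or more. DNA replication genes have medians of -0.36 and -1.83, and ribosomal protein genes 0.22 and 0.38.

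Interferon-stimulated genes moved in both directions, and their list passed in neither comparison. With shRNA 1, 11 of 47 were higher and 8 lower (the same counts adjusted over the list alone), per the authors' deposited table. This gave a median of 0.17 and a list adjusted p of 0.407. With shRNA 2, 13 of 51 were higher and 12 lower (15 and 14 adjusted over the list alone), per the authors' deposited table. Over the list the median was 0.26, and its adjusted p was 0.573. Among 10000 random lists of matched mean expression, these medians lay at the percentiles 99.97 and 100, so that the median lay high while the list test did not pass, nor its rank-based form (adjusted p of 0.0754 and 0.314). SAMD9L was at -0.67 ± 0.10 and -0.56 ± 0.10, and the antiviral GTPase MX1 at 0.47 ± 0.14 and -0.47 ± 0.14 (SE) with shRNA 1 and shRNA 2 in the authors' deposited tables. Direct antiviral targets of IRF3 were higher in 2 and lower in 1 of 12 cases with shRNA 1 and higher in 1 and lower in 3 of 13 with shRNA 2 (identical adjusted over the list alone), with list adjusted p-values of 0.560 and 0.307, from the authors' deposited tables. Within that list, the exonuclease gene ISG20 was at -0.36 ± 0.13, a call lost without the filter on low genes and on recentring, and -1.29 ± 0.13, and the chemokine gene CCL5 at 0.33 ± 0.14, which did not pass, and -1.17 ± 0.15 (SE) in the authors' deposited tables. In the nucleic acid sensing pathway, IKBKE, a kinase that activates IRF3, was at 0.61 ± 0.10 and 0.50 ± 0.10 and ZBP1 at -0.31 ± 0.09 and -0.51 ± 0.09 (SE) in the authors' deposited tables. That list had 2 higher and 5 lower of 21 (2 and 6 adjusted over the list alone), and 6 higher and 3 lower of 22 (8 and 6), with list adjusted p-values of 0.681 and 0.592 on the authors' deposited statistics.

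Genes changed with both hairpins in the same direction are what the pair of hairpins offers. They included lower IRF4, XBP1, PRDM1, SEL1L and SCD and higher ribosomal protein genes, IL2RG, BMF, FAS and TNFRSF10B. Of 14488 genes with an adjusted p in both of the authors' deposited tables, 1377 passed in both with the same sign, 491 higher and 886 lower, and 370 passed with opposite signs. Recentred on the median gene, the 1323 such genes split into 620 higher and 703 lower, so the share of higher genes moved from 35.7% to 46.9%. Among genes with a mean of 50 or more, the phosphatase receptor PTPRF (chromosome 1, 43525187 to 43623666) was at 2.25 ± 0.16 and 2.05 ± 0.16, and the microtubule-associated gene MAPT at 1.77 ± 0.20 and 1.66 ± 0.20 (SE) in the authors' deposited tables. ITGAM, NEK11 and the lymphoid antigen CD7 were at 2.85, 1.95 and 1.76 with shRNA 1 and at 2.03, 1.80 and 1.77 with shRNA 2 in the authors' deposited tables. FCGBP, TGM5, FRMD1, DOK7, DMTN and DMBT1 were also among the 12 largest, with log2 fold changes from 1.67 to 3.37 in the authors' deposited tables. RSC1A1 is listed at 8.28 ± 1.56 and 8.97 ± 1.56 (SE) in the authors' deposited tables, but its reconstructed scramble mean was 0.188 normalised read counts and its exons overlap DDI2, so this is not a measured size. PECAM1 (chromosome 17, 64319415 to 64413776), an adhesion molecule, was at -2.55 ± 0.26 and -1.92 ± 0.25, the receptor kinase TYRO3 at -1.67 ± 0.22 and -2.37 ± 0.22, and TIAM1, a Rac activator, at -1.44 ± 0.16 and -1.44 ± 0.16 (SE) in the authors' deposited tables. The chemokine gene CCL3L1 was at -2.03 ± 0.11 and -2.99 ± 0.11 (SE) in the authors' deposited tables, with the division of reads between it and its close copy CCL3 uncertain. The transcriptional repressor GFI1 was at -1.42 and -2.61, and LRRC20, RHBDL3, CEP128, ITPKA, C3orf70, NIBAN1 and SH3BGRL2 lay between -2.14 and -1.46 in the authors' deposited tables.

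The pro-apoptotic gene BMF was at 0.92 ± 0.08 and 1.30 ± 0.08, BAX at 0.56 ± 0.11 and 0.44 ± 0.11, and the cytokine receptor chain IL2RG at 0.89 ± 0.08 and 0.92 ± 0.08 (SE) in the authors' deposited tables. MYC, at 0.22 ± 0.08 and 0.09 ± 0.08 (SE), passed with shRNA 1 (DESeq2 adjusted p of 0.0378, a call lost without the filter on low genes) and not with shRNA 2 (0.523) in the authors' deposited tables. Independent lists of these sizes would share 177 higher and 453 lower genes and hold 567 with opposite signs. Both comparisons use the same scramble libraries. Across 12977 genes with a mean of 50 or more, which are not independent replicates, the correlation of the deposited log2 fold changes was 0.340, below the 0.502 of simulated unchanged groups against shared controls. The covariance was 0.0951 against a simulated 0.0279, a difference of 0.0672. Of these genes, 60.4% had the same sign in both, against 66.6% in the simulation. Changes particular to 1 hairpin, absent from the simulation, lower both the correlation and the share of equal signs. Values below the simulated ones therefore do not speak against shared changes. At the threshold of 0.05, 0 simulated genes passed in both, in groups simulated with no effect. When as many top genes were drawn from each simulated comparison as were called in the data, a mean of 1559 (1502 to 1615) lay in both in the same direction and 80.2 in opposite directions. Neither value tells how many of the 1377 genes owe their shared direction to the scramble libraries, of which 2 are too few to be split.

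**Figure D3:**
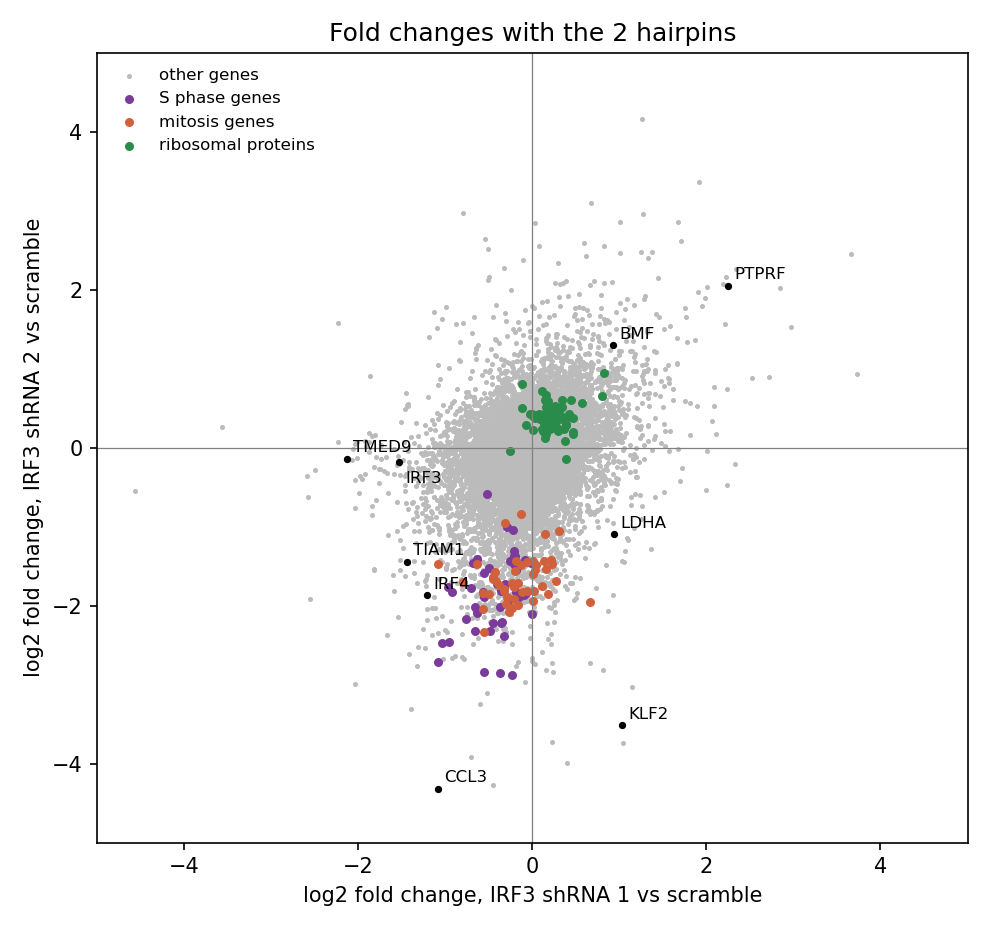
Each point is a gene with a mean of at least 50 normalised read counts, with its log2 fold change with shRNA 1 on the horizontal and in the libraries labelled shRNA 2 on the vertical axis, from the authors' deposited tables; 2 of 12977 genes lie outside the axes. S phase (purple) and mitosis (orange) genes lie far below 0 on the vertical axis, with medians of -1.83 and -1.70, and ribosomal protein genes (green) have medians of 0.22 and 0.38.

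The last comparison asked where the hairpins differed. Cell cycle genes were much lower with shRNA 2 than with shRNA 1, and KLF2, LDHA, ANXA2 and the MHC class II genes HLA-DPA1 and HLA-DRA went up with shRNA 1 and down with shRNA 2. By a two-sided z test on the authors' deposited values, 3471 of 14488 genes differed at an adjusted p below 0.05, 1470 higher and 2001 lower with shRNA 2. The test ignores the shared scramble libraries and is conservative. With 0.5 of each variance removed from the SE the count was 5724, and with an SE reconstructed from both tables, an alternative chosen after seeing the data, it was 5715. The 4 genes with the lowest p were CCL3 (chromosome 17, 36088256 to 36090169), KLF2 (chromosome 19, 16324817 to 16327874), LDHA (chromosome 11, 18394388 to 18408425) and ANXA2 (chromosome 15, 60347134 to 60402883). CCL3, a macrophage inflammatory chemokine gene, was at -1.09 ± 0.11 and -4.32 ± 0.12, and the phospholipid-binding annexin ANXA2 at 0.85 ± 0.10 and -1.48 ± 0.10 (SE) with shRNA 1 and shRNA 2 in the authors' deposited tables. Adjusted p-values of the difference, from the authors' deposited values, were 8.99e-84 for CCL3, 9.36e-75 for KLF2, 4.52e-73 for LDHA and 5.92e-60 for ANXA2. IRF4 was lower with shRNA 2 than with shRNA 1 by -0.66 ± 0.12 (SE), with an adjusted p of 5.44e-07, whereas the difference for XBP1 did not pass (adjusted p of 0.0568, and 0.00215 with the reconstructed SE), on the authors' deposited values.

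Of the tested lists, 9 differed between the hairpins by cameraPR on the z of the difference. DNA replication genes (adjusted p of 8.59e-44) and mitosis genes (1.72e-32) were lower with shRNA 2 in 46 of 48 and 46 of 47 cases. MHC class II genes (3.83e-06) were lower with shRNA 2 in 11 of 16 cases, and 3 were higher and 6 lower than scramble with shRNA 2 (3 and 7 adjusted over the list alone), with a median of -0.16 and a list adjusted p of 0.365, from the authors' deposited tables. HLA-DRA was at -0.38 ± 0.09 and HLA-DPA1 at -0.90 ± 0.12, whereas HLA-DQA1 was higher at 1.53 ± 0.37 (SE) with shRNA 2 in the authors' deposited table. Hypoxia and glycolysis genes (2.58e-13), immediate early genes (1.18e-12) and genes of the cyclin D and CDK list (2.27e-06) were lower with shRNA 2 in 17 of 27, 15 of 25 and 9 of 19 cases. For the cyclin D and CDK list, 5 of 19 were higher and 2 lower with shRNA 1 (the same counts adjusted over the list alone), with a list adjusted p of 0.456 on the authors' deposited statistic. The plasma cell (0.00323), cholesterol (0.0173) and ribosomal protein (0.000170) differences became 0.0566, 0.129 and 0.0523 with a preset correlation of 0.05.

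Some of the largest changes passed with 1 hairpin and not with the other. With shRNA 1, DNM1, TNFRSF25, ARVCF and LINC02363 were higher, at 3.73, 2.52, 2.33 and 2.24, and SRPK3, the cannabinoid receptor CNR1, TMED9 and OPLAH lower, at -2.50, -2.24, -2.13 and -2.07, in the authors' deposited table. In that order, their SEs were 0.56, 0.36, 0.31, 0.44, 0.54, 0.42, 0.09 and 0.52. The difference from shRNA 2 passed for each of these 8 except LINC02363 (adjusted p of 0.0718, and 0.00168 with the reconstructed SE), by the z test on the authors' deposited values. With shRNA 2, the matrix metalloproteinase MMP9, RUNDC3A, GPR35 and TENM4 were higher, at 4.16, 3.10, 2.98 and 2.96, and ETV5, SMCO4, LOC102724219 and ZNF367 lower, at -4.00, -3.92, -3.72 and -2.97, in the authors' deposited table. Their SEs, in that order, were 0.91, 0.38, 0.55, 0.61, 0.79, 0.41, 0.67 and 0.17, so several of these sizes are imprecise. The difference passed for each of these 8 except MMP9 (0.0868) and TENM4 (0.157), which passed with the reconstructed SE (0.00431 and 0.00965). Of the 14488 genes with an adjusted p in both tables, 1824 passed with shRNA 1 and not with shRNA 2, 712 higher and 1112 lower, and 3108 the other way round, 1158 higher and 1950 lower, per the authors' deposited tables. Annotated exons of TNFRSF25, ARVCF, SRPK3, OPLAH, RUNDC3A and GPR35 overlap those of a neighbouring gene, which makes their levels uncertain.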

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

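Results are listed here because the test of the difference between the hairpins passed, although both were directed at the same gene. The tests of seed pairing, of the whole cause, of coding direction and of replicate noise were chosen after the results were seen, while those of the scramble hairpin and of a deviation common to the scramble libraries were set before.

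The log2 fold change of IRF3 was higher with shRNA 2 than with shRNA 1 by 1.35, and 3471 genes differed. KLF2, CCL3, ANXA2 and LDHA differed by -4.55, -3.23, -2.34 and -2.03, shRNA 2 minus shRNA 1. The median difference was -1.42 for DNA replication genes, -1.52 for mitosis genes and -0.67 for the cyclin D and CDK list. It was -1.13 for MHC class II, -0.69 for immediate early genes, -0.59 for hypoxia and glycolysis, -0.36 for cholesterol synthesis, -0.14 for plasma cell genes and 0.17 for ribosomal protein genes.

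The first pattern weighed is the 1112 genes that were lower with shRNA 1 and not called with shRNA 2, with TMED9 among them, for which a candidate explanation is off-target pairing of the shRNA 1 guide through its seed, as microRNAs pair with 3' UTRs. The sequence GTGAGGC had the lowest z of all 7-base sequences, -9.64 over 1018 genes with it in their 3' UTR, against a lowest of -5.39 in 200 permutations. The mean residual log2 fold change of these genes was -0.127, small beside the -2.13 of TMED9. An average over many genes does not tell the size of an effect in a single gene. TMED9 holds at least 1 of the 2 leading sequences of this scan in its 3' UTR. With shRNA 2 it was at -0.14 ± 0.09 (SE), with a DESeq2 adjusted p of 0.271 in the authors' deposited table. Chosen on either set of chromosomes, GTGAGGC ranked first in the other, the weaker z being -6.47, although these sets are parts of data already scanned. Its z with shRNA 2 was -1.03. With the second sequence, TGAGGCA, it forms GTGAGGCA, which lies in the coding part of 9 of 14 IRF3 transcripts (chromosome 19, 49662142 to 49662149, GRCh38), as 3.47% of all 8-base sequences lie in IRF3 transcripts. Of 1045 searched genes of the pattern, 36.4% held a site, against 20.2% of genes called in neither comparison. The sequences were chosen on the same fold changes, so this excess is no separate support. Most of these genes held neither of the 2 sequences, so pairing at these 2 in the searched 3' UTRs does not directly account for all of them. Overlapping sequences such as TGAGGCT (z of -7.04), sites outside 3' UTRs and indirect effects were not counted. The share therefore cannot exclude off-target action as the whole cause. An effect of IRF3 loss, which was not shown with shRNA 2, stays open.

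The second pattern is that no fall of IRF3 was detected in the libraries labelled shRNA 2, while cell cycle genes fell. The interval of the IRF3 ratio, 0.768 to 1.01, leaves room for a modest fall. A table coded in the opposite direction is argued against by the dispersions, whose median absolute log ratio rose to 0.169 with the sign turned, from 0.00671. Seed pairing is a candidate for part of the changes in these libraries. GGGACAT had the lowest z, -6.14 over 892 genes against -5.14 in permutations, and the weaker z between chromosome sets was -4.26. The mean residual log2 fold change of genes with GGGACAT was -0.117, against medians of -1.83 and -1.70 for DNA replication and mitosis genes. Whether cell cycle genes hold such sites more often was not tested, and the scan does not address the level of IRF3. Action of the passenger strand of an IRF3 hairpin cannot be told apart from another active sequence, because the reverse complement ATGTCCCT of AGGGACAT lies in 9 of 14 IRF3 transcripts (coding part, chromosome 19, 49662175 to 49662182), but that of the sequence ranked second, AAGGGAC, lies in 0. A wrong label, recovery of IRF3 mRNA by the time of harvest and an effect on IRF3 protein alone stay open and untested.

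The third pattern is the 1377 genes changed by both hairpins in the same direction, IRF4 among them. Replicate noise of the shared scramble libraries as the whole cause is argued against, for noise independent between genes, by a covariance of 0.0951 ± 0.00698 (bootstrap SE over genes). The mean variance of the scramble mean, reconstructed from the SEs, was 0.0279. The bootstrap takes genes as independent, so its SE understates the spread if many genes vary together, and such noise is not excluded. A seed effect of the scramble hairpin would raise genes with its sites in both comparisons, and the highest z against the mean of both fold changes was 4.03, within the 5.04 reached by permutations. A deviation common to both scramble libraries cannot be told apart from an effect of the hairpins, since both comparisons use them and 24.8% of these genes (342) differed between the hairpins, which neither excludes nor requires it. An effect of IRF3 loss stays among the open explanations for shRNA 1, but a fall of IRF3 mRNA was not shown for shRNA 2. Seed pairing of the 2 IRF3 hairpins also stays open, and no test of it was set for these genes. Over all scanned genes, the lowest z against the mean of both fold changes was -5.75, for GTGAGGC. This lay below the -5.06 reached by permutations. The z of GTGAGGC was -9.64 with shRNA 1 and -1.03 with shRNA 2, so the low value came mainly from shRNA 1. Of 867 searched genes lower with both, 36.2% held a leading sequence of the shRNA 1 scan and 21.6% one of the shRNA 2 scan. Genes called in neither held them in 20.2% and 13.7% of cases, but the sequences were chosen on these fold changes. IRF4 holds a leading sequence of the shRNA 2 scan in its 3' UTR but none of the shRNA 1 scan in any searched transcript. The genes named for the largest changes with both hairpins were searched in their 3' UTRs. Of the lower ones, PECAM1, TYRO3, LRRC20, RHBDL3, CEP128, C3orf70, NIBAN1, SH3BGRL2 and TIAM1 hold a leading sequence of the shRNA 1 scan. CCL3L1, ITPKA and GFI1 hold none of either scan. Of the higher ones searched, FRMD1 alone holds a sequence of the shRNA 1 scan. SEL1L and SCD, named as list members, hold a sequence of each scan. The same fold changes picked these genes and the sequences, so the contrast is descriptive and was not tested.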

How the results depend on the processing

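The reconstructed SE, the recentring of the shared genes, the longest 3' UTR and the list without IRF3 were chosen after seeing the data. No paired analysis was possible because the tables used here hold no value of a single library; for the same reason the planned count tests, pseudocounts, 2-group fits and fits without a replicate were not run. Where the number of genes moved by over 1.5 times, a stricter or looser rule set it by construction. With an absolute log2 fold change of at least 1, 524 genes passed with shRNA 1, 1367 with shRNA 2 and 134 with both in the same direction (71 higher and 63 lower, against 491 and 886 with no minimum). With at least 0.5, 2002 passed with shRNA 1, 3191 with shRNA 2 and 638 with both. At an adjusted p below 0.01, 869 genes passed with both. Genes that differed between the hairpins numbered 5724 with 0.5 of each variance removed from the SE and 5715 with the reconstructed SE. Lists called with shRNA 1 fell from 15 to 9 with a preset correlation of 0.05 and to 7 when ranked by log2 fold change (the cause of the latter was not tested), and ranged from 11 to 12 with shRNA 2. Recentring gave 3533 genes (1699 higher) and 4951 genes (2158 higher), and IRF3 log2 fold changes of -1.49 and -0.14. Of 906 values of named genes under 3 alternatives, 881 kept their side of the threshold and 25 did not, 0 of them with a change of direction; 13 lost the call with no filter on low genes, namely AGO4, BCL3, CDK6, HLA-B, IER5, IRF7, ISG20, JUNB, MYC and TNRC6C with shRNA 1, and CD70, HIST1H1C and ND4 with shRNA 2, and 5 of these also on recentring. Leading sequences of the scan were identical with the longest 3' UTR (z of -10.4 and -6.34). A median SE of 0.36 at means of 50 to 200 limits what can be said of low genes.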

Other observations

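Several lists fixed before the data were examined showed members that moved without the list passing. MHC class I genes had 3 higher and 5 lower of 20 with shRNA 1 (4 and 6 adjusted over the list alone), and 2 and 5 of 20 with shRNA 2 (2 and 5), with list adjusted p-values of 0.332 and 0.669 on the authors' deposited statistics. The non-classical HLA-E was at -0.65 ± 0.08 and -0.38 ± 0.08, and the peptide-loading gene TAPBP at -0.26 ± 0.08 and -0.40 ± 0.08 (SE) in the authors' deposited tables. MYC target and ribosome biogenesis genes had 9 higher and 7 lower of 43 (11 and 8 adjusted over the list alone), and 1 and 9 of 43 (1 and 9), with adjusted p-values of 0.208 and 0.307. Within that list, ODC1, of polyamine synthesis, was at 0.40 ± 0.09 and -0.47 ± 0.09, and the transferrin receptor TFRC at 0.40 ± 0.09 and -0.43 ± 0.10 (SE) in the authors' deposited tables. BCL2 family, death receptor and caspase genes had 8 higher and 9 lower of 30 (8 and 9 adjusted over the list alone), and 8 and 6 of 30 (8 and 7), with adjusted p-values of 0.821 and 0.149. IL-6 and STAT3 signalling genes had 2 higher and 4 lower of 17, and 4 and 3 of 17, the same adjusted over the list alone, with adjusted p-values of 0.821 and 0.640. The signal-transducing receptor IL6ST was at -0.43 ± 0.09 and -0.92 ± 0.09, and the IL-6 receptor IL6R at -0.29 ± 0.09 and 0.73 ± 0.09 (SE) in the authors' deposited tables. Earlier B lineage markers had 1 higher and 0 lower of 10, and 2 and 1 of 11, the same adjusted over the list alone, with adjusted p-values of 0.407 and 0.625; CD79B was at -0.19 ± 0.13, which did not pass, and 0.39 ± 0.13 (SE) in the authors' deposited tables.

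RNA interference genes had 2 higher and 2 lower of 14 with shRNA 1, and 1 and 6 of 14 with shRNA 2, the same adjusted over the list alone, with list adjusted p-values of 0.863 and 0.295 on the authors' deposited statistics; AGO4 was at -0.38 ± 0.15 and -0.59 ± 0.15 (SE) in the authors' deposited tables. Besides MHC class II, whose difference between hairpins passed, lists that passed with shRNA 1 and not with shRNA 2 were NF-kappaB targets (10 higher and 2 lower of 26 with shRNA 2, 11 and 3 adjusted over the list alone, adjusted p of 0.718), ligands of NK and T cells (6 and 6 of 18, unchanged over the list alone, 0.961) and mitochondrial genes (1 and 5 of 13, unchanged over the list alone, 0.561). The same held for histones (1 and 3 of 17, 1 and 1 adjusted over the list alone, 0.669, and 0.00314 when ranked by log2 fold change) and the interferon regulatory factor family (2 and 1 of 9, unchanged over the list alone, 0.522); the differences between hairpins did not pass for these 5 lists. Targets of ATF4 and CHOP had 5 higher and 5 lower of 29 with shRNA 1 (5 and 6 adjusted over the list alone), with an adjusted p of 0.821. Neighbours of IRF3 had list adjusted p-values of 0.942 and 0.827. Median, mean and test differed in sign in 6 cases that did not pass, the BCL2 family list in both comparisons, IL-6 and STAT3, IRF3 neighbours and RNA interference with shRNA 1, and the interferon regulatory factor family with shRNA 2. Markers of other cell types were mostly too low to test. T and NK cell markers had 2 and 3 tested members, and myeloid and stromal markers 4 each with shRNA 1. With shRNA 2, myeloid markers had 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone, adjusted p of 0.307, and 0.0422 when ranked by log2 fold change), and stromal and epithelial markers 1 higher and 2 lower of 8 (2 and 2 adjusted over the list alone, adjusted p of 0.843), from the authors' deposited tables.

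Sites of the leading shRNA 1 sequences were found in 36.2% of 867 searched genes lower with both hairpins and in 18.5% of 1818 genes lower with shRNA 2 and not called with shRNA 1, against 20.2% of genes called in neither. Sites of the leading shRNA 2 sequences were found in 21.6% of the former and 18.6% of the latter, against 13.7% of genes called in neither. These shares are descriptive and no test is given, because the sequences were chosen on the same fold changes that define the sets of genes, and longer 3' UTRs hold more sites of any sequence.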
